A study of Mus musculus with 4 samples.

How the data were processed

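RNA from Langerhans cells sorted out of epidermal cell suspensions was extracted with Trizol and made into libraries with the NEBNext Ultra RNA kit, per the labels' protocols. The labels do not state whether RNA was selected by its poly(A) tail or whether strand was kept. The deposited values are FPKM, fragments per kilobase of transcript scaled to the mapped fragments of the library, computed by the authors with Cufflinks per the file headers, in 1 table per library with the 95% interval of each estimate. CASAVA, Cufflinks and the build mm10 are named, without versions, per the submitters' processing notes, and the aligner and the gene annotation are not given in the sources used here. The gene positions in the tables did not match that build. Of 23597 symbols shared with the GENCODE annotation of GRCm38, 11.4% had a position overlapping the gene of that name. Coordinates are therefore given as the files have them, with the build unresolved.

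Each table had 24994 rows for 24441 symbols. FPKM of the 301 symbols listed at several loci, 854 rows, were summed. Symbols with a mean of at least 1 FPKM over the 4 libraries were tested, 10910 in all. Values were transformed as log2(FPKM + 1), so that fold changes of genes with low levels are understated. Tfam cKO was compared with WT, 2 libraries each, in limma 3.58.1 under R 4.3.3, with genotype as the only term, moderated variances with a mean trend, and Benjamini-Hochberg adjustment at 0.05. A design for whole read counts had been written as well, but the tables held FPKM, so the design for FPKM was used.

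In the tables read depth is not recorded. Cufflinks' interval spans 2 standard errors on each side, so its width gives an effective number of fragments behind each value. For 74 of 9645 genes with between 5 and 1000 such fragments this number was whole in all 4 libraries, within 0.02, and their ratios gave the relative depth, which ranged from 0.884 to 1.56 with WT 1 set at 1. Fragment numbers and intervals cover counting error only.

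Before the data were examined, 37 gene lists were fixed for pathways, quality and other cell types. The 29 lists with at least 5 tested members were tested with camera at a preset inter-gene correlation of 0.01, which compares a list with all other genes, and beside it with an estimated correlation and with fry. Lists were adjusted over the 29, and members also over each list alone. The text names Tfam, Cd207, Epcam, and in each direction the 8 genes of largest change among those past the threshold with separate group ranges, at least 5 FPKM in the higher group and a regular gene symbol. Where fewer passed, the next genes by unadjusted p were taken and are given as not past the threshold. Each list adds up to 4 members past the threshold, or else the 2 of highest level. A gene that the rule selects is not reported here. Genes outside this rule are said to have been chosen after their values were seen. A camera call can differ in sign from the list's own median, because camera sets it against the other genes.

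The test was tested on simulated data with 2 libraries per group and the fitted variances, for the comparison of Tfam cKO with WT over 10910 genes. It recovered 70% of genes changed 2-fold, 98% of those changed 4-fold and 100% of those changed 8-fold and 16-fold, of 50 each, with 10 false calls among 10710 unchanged genes. All these genes were changed in the same simulated data, which makes the adjusted threshold easier to pass than where few genes change. The shares therefore do not carry over to the data. There C1qc, with a log2 fold change of 2.07, did not pass (limma adjusted p = 0.115). The list test called 100 of 100 lists shifted by 0.3 and 2 of 100 unshifted lists at p below 0.05. Genes were simulated as independent, so this does not give its error rate for correlated genes. In the data the estimated correlation was 0.172 for the list of ATF4 targets and 0.768 for the cell cycle list.

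Alternatives were quantile normalization, rescaling to equal totals (TPM), no filter, a filter at 5 FPKM, pseudocounts of 0.1 and 5, no mean trend, robust moderation, the replicate number as a block, other thresholds, leaving out markers of other cell types, and leaving out each library in turn. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.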

Results

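Gene expression was measured by RNA sequencing in Langerhans cells, the antigen-presenting cells of the epidermis, sorted from the skin of mice at 4 weeks of age. The 2 groups were wild-type mice (WT) and mice carrying a CD11c-Cre transgene with floxed Tfam alleles (Tfam cKO), so that the gene for the mitochondrial transcription and DNA-packaging factor TFAM is targeted in CD11c-expressing cells. Each group had 2 libraries, numbered 1 and 2 in the labels. The labels do not say which mice each library came from, and p-values measure only the spread between these libraries, moderated by that of other genes. The libraries of a group were not repeats of the same RNA, since in each group Y-linked transcripts were listed at 0 in library 1 and were present in library 2. Expression was given as FPKM for 24441 gene symbols, of which 10910 had a mean of at least 1 FPKM and were tested. Total read numbers are unknown, but whole fragments could be recovered for 74 genes and placed the depth of WT 2, Tfam cKO 1 and Tfam cKO 2 at 1.37, 0.884 and 1.56 times that of WT 1. Across genes, which are not independent replicates, log2 values of the WT libraries correlated with r = 0.977, those of the Tfam cKO libraries with r = 0.976, and libraries of different groups with r between 0.971 and 0.981.

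The targeted gene was examined first, as a check of the labels. Tfam was listed at 3.17 FPKM in WT 1, 1.61 in WT 2, 1.65 in Tfam cKO 1 and 1.53 in Tfam cKO 2. WT 2 was therefore at the level of the Tfam cKO libraries, and Tfam did not separate the groups (log2 fold change −0.35, SE 0.25, limma adjusted p = 0.90). Cufflinks' 95% interval was 1.30 to 1.92 in WT 2 and 1.26 to 2.04 in Tfam cKO 1. A gene-level value can include reads from outside the deleted part of a floxed allele, so it neither establishes nor contradicts the deletion. WT and Tfam cKO below name the libraries by their labels, and every direction rests on those labels. Within the libraries numbered 1 the Tfam log2 difference was −0.66 and within those numbered 2 it was −0.05. Without WT 1, the fold change was −0.01. Tfam lies at chromosome 10, 70688225 to 70700792, in the coordinates of the files, whose build could not be matched to the mm10 named in the processing notes. The mRNAs encoded by mitochondrial DNA, whose transcription needs TFAM, were not analysed here.

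No difference in Langerhans cell identity genes was detected between the groups. Cd207, which encodes langerin, averaged 1796 ± 427 FPKM (SD, n = 2) in WT and 1451 ± 109 FPKM (SD, n = 2) in Tfam cKO, with a log2 fold change of −0.29 (SE 0.26, limma adjusted p = 0.92). Epcam, an adhesion molecule of epidermal Langerhans cells, averaged 191 ± 11.9 and 186 ± 9.09 FPKM (SD, n = 2 each), with a log2 fold change of −0.04 (limma adjusted p = 0.99). Csf1r, the receptor for IL-34 and M-CSF, averaged 224 ± 35.3 FPKM in WT and 228 ± 30.3 FPKM in Tfam cKO. None of the 25 tested identity genes passed the test, either over all genes or adjusted over the list alone, and the list median was 0.01 (camera adjusted p = 0.52) and −0.11 after rescaling all libraries to equal totals.

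Over all tested genes, 2 were higher and 0 were lower in Tfam cKO at a limma adjusted p below 0.05. Rmrp, the RNA component of the RNase MRP endoribonuclease, rose from 1.88 ± 0.823 to 21.8 ± 4.19 FPKM (SD, n = 2 each; log2 fold change 3.0, SE 0.23, limma adjusted p = 0.00916). Its Cufflinks intervals correspond to 1 and 1 fragments in WT and 9 and 9 in Tfam cKO, a depth-scaled ratio of 8.73 with an exact 95% Poisson interval of 2.09 to 77.6 that covers counting error only. Amd1, a gene for S-adenosylmethionine decarboxylase of polyamine synthesis, was listed at 0.0265 and 0.0197 FPKM in WT and at 9.79 and 5.49 FPKM in Tfam cKO (log2 fold change 3.03, SE 0.26, limma adjusted p = 0.0103). Its call is uncertain, because in the files the Amd1 model, at chromosome 10, 40007264 to 40021994, covers the same stretch as Amd2, so that reads could be divided between them. Amd2 was listed at 35.1 and 32.9 FPKM in WT and at 32.2 and 38.4 FPKM in Tfam cKO. Within the libraries numbered 1 and those numbered 2, the log2 differences were 2.90 and 3.11 for Rmrp and 3.39 and 2.67 for Amd1. The size of both changes depended on the pseudocount, with a log2 fold change of 3.52 for Rmrp and 5.92 for Amd1 at 0.1 and of 1.96 and 1.31 at 5. For Amd1 it was 4.23 after rescaling to equal totals of 1e+06. The pseudocount of 1 weighs less there than at the deposited totals of 338783 to 395707, so this value is not an effect of scaling alone. Neither call held without a low-value filter, where 16426 genes were tested (adjusted p = 0.856 for both), and that of Amd1 ended with a pseudocount of 5 (0.0746, in a range over its alternatives of 8.6e-22 to 0.856). At an unadjusted p below 0.05 there were 547 genes higher and 130 lower, 677 together, where 546 would be counted by chance. Splitting the same libraries by replicate number gave 676 such genes, so the excess is not particular to genotype. The remaining split, WT 1 with Tfam cKO 2 against WT 2 with Tfam cKO 1, gave 226. The division into higher and lower genes by genotype depended on the scaling, with 334 higher and 245 lower after quantile normalization and 281 higher and 293 lower after rescaling to equal totals. The share of tested genes with a positive fold change was 65.2% as deposited, 48.2% after quantile normalization and 43.2% after rescaling, which moved the median of all genes by −0.11. With a library left out, the lone library of a group is assumed to vary like the other group, so counts from those fits do not compare with these. Y-linked transcripts split the libraries by replicate number, and a limma fit with that number as a term gave 145 genes higher and 39 lower. That fit leaves fewer than the 2 residual degrees of freedom per gene of the main fit, so its p-values lean more on variances pooled over genes. The term does not balance sex-linked transcripts, since Xist was listed at 5.38 FPKM in WT 2 and at 45.6 FPKM in Tfam cKO 2.

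The genes next in rank reported here among those higher in Tfam cKO did not pass the adjusted threshold. Only genes with both Tfam cKO libraries above both WT libraries were ranked, so that separation is a condition of their choice. Rab7b, a lysosomal small GTPase, averaged 12.0 ± 0.0861 FPKM in WT and 30.4 ± 2.4 FPKM in Tfam cKO (SD, n = 2 each; log2 fold change 1.27, limma adjusted p = 0.115). C1qc, a chain of complement C1q, averaged 2.30 ± 0.784 and 13.2 ± 5.48 FPKM (log2 fold change 2.07, limma adjusted p = 0.115), with log2 differences of 2.72 within the libraries numbered 1 and 1.42 within those numbered 2. Rpph1, the RNA component of RNase P, averaged 4.94 ± 1.05 and 18.3 ± 6.41 FPKM. Cyba, a subunit of the NADPH oxidase, averaged 19.4 ± 0.647 and 43.4 ± 4.42 FPKM, and Hs3st1, a heparan sulfate sulfotransferase, 16.8 ± 1.84 and 37.1 ± 0.854 FPKM. The limma adjusted p was 0.149 for Rpph1, Cyba and Hs3st1. Both other C1q chains, chosen after their values were seen, had the same order of libraries, C1qa at 22.1 and 29.3 FPKM in WT and 88.5 and 55.2 in Tfam cKO, and C1qb at 2.28 and 3.03 in WT and 22.1 and 9.46 in Tfam cKO. Rab7b, C1qc, Rpph1, Cyba and Hs3st1 each passed with the replicate number as a term (limma adjusted p from 1.2e-09 to 4.9e-05). Those values rest mainly on variances pooled over genes, not on the spread of each gene. Rab7b also passed with robust moderation (0.0458). None passed without a low-value filter (0.856). Leaving out a library leaves 1 in a group, so only fold changes are given for those fits. Over all alternatives, these fits included, the log2 fold change ranged from 1.06 to 1.35 for Rab7b and from 1.29 to 2.47 for C1qc. It ranged from 1.21 to 2.02 for Rpph1, from 0.988 to 1.22 for Cyba and from 0.951 to 1.21 for Hs3st1.

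No gene with a lower level in Tfam cKO passed the threshold. The 8 genes next in rank were taken only from genes with both Tfam cKO libraries below both WT libraries, so that separation is a condition of their choice. Hap1, which encodes huntingtin-associated protein, averaged 14.2 ± 2.02 FPKM in WT and 5.03 ± 0.524 FPKM in Tfam cKO (SD, n = 2 each; log2 fold change −1.33, limma adjusted p = 0.115). The chemokine gene Ccl1 averaged 7.82 ± 2.37 and 2.05 ± 0.518 FPKM (log2 fold change −1.51, limma adjusted p = 0.149), a value resting on 32 fragments in WT 1, 30 in WT 2, 5 in Tfam cKO 1 and 12 in Tfam cKO 2. Pla2g5, a secreted phospholipase A2, averaged 23.3 ± 2.80 and 10.1 ± 1.78 FPKM. The neutrophil chemokine gene Cxcl2 averaged 281 ± 26.4 and 134 ± 20.6 FPKM. Clec7a, the beta-glucan receptor Dectin-1, averaged 75.3 ± 3.86 and 34.5 ± 9.84 FPKM. Cox6b2, a testis-enriched subunit of cytochrome c oxidase, averaged 8.30 ± 0.434 and 4.43 ± 0.275 FPKM. Tmem176a, a transmembrane protein gene of dendritic cells, averaged 22.0 ± 3.39 and 11.3 ± 1.83 FPKM. Ccr7, the chemokine receptor that guides dendritic cells to lymph nodes, averaged 8.12 ± 2.19 and 3.70 ± 0.660 FPKM. For the genes from Pla2g5 to Ccr7, limma adjusted p ranged from 0.160 to 0.417. Each of the 8 passed with the replicate number as a term (limma adjusted p from 1.8e-06 to 0.0105), again with values resting mainly on variances pooled over genes. Hap1 also passed with robust moderation (0.0469). None passed without a low-value filter (0.856). With a library left out, 1 stands alone in its group, so only fold changes are given for those fits. Over all alternatives, these fits included, the log2 fold change ranged from −1.54 to −0.93 for Hap1 and from −1.87 to −0.85 for Ccl1. It ranged from −1.30 to −0.905 for Pla2g5, from −1.22 to −0.908 for Cxcl2 and from −1.42 to −0.846 for Clec7a. For Cox6b2 the range was −0.97 to −0.496, for Tmem176a −1.065 to −0.731 and for Ccr7 −1.19 to −0.585.

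**Figure D1:**
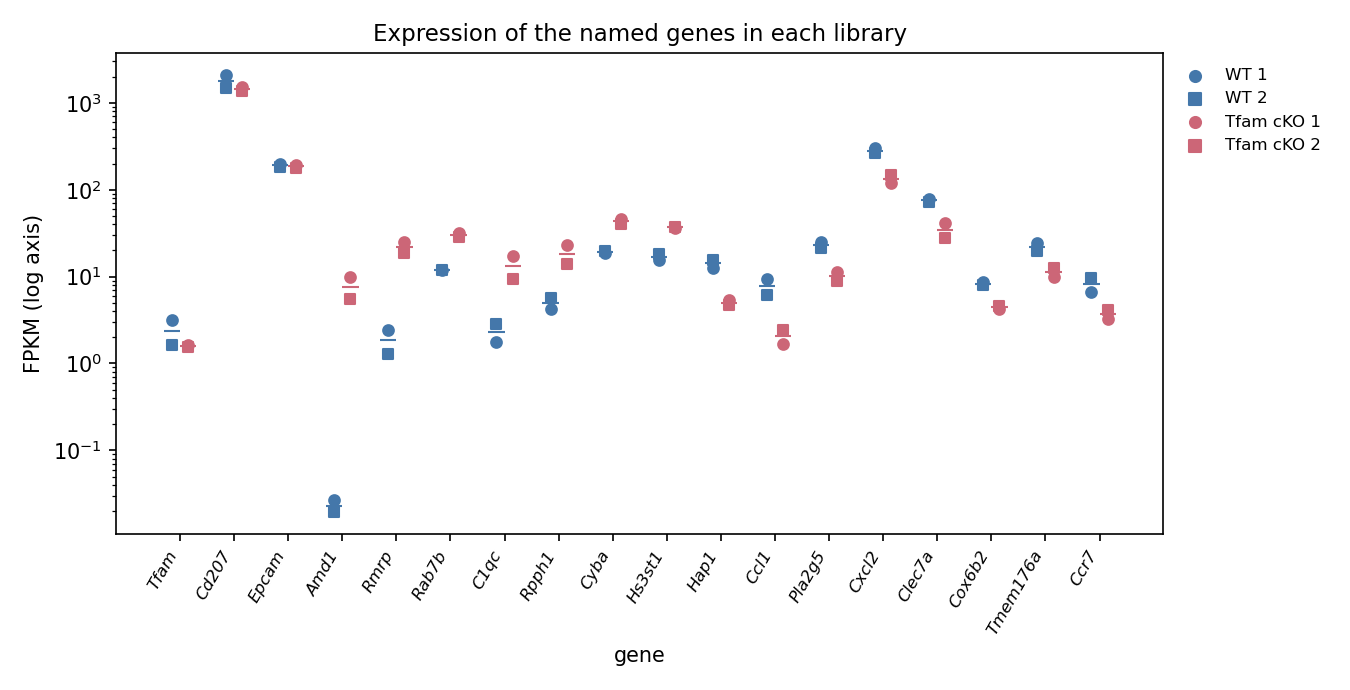
FPKM (log axis) of Tfam, Cd207, Epcam and the highest-ranked genes reported in each direction, with 1 point per library (circles for replicate 1, squares for replicate 2) and a line at each group mean. Rmrp and Amd1 passed the test, and the WT 2 value of Tfam, 1.61, lies next to the Tfam cKO values of 1.65 and 1.53.

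Of the gene lists fixed before the data were examined, 29 had enough tested members, and camera with a preset inter-gene correlation placed 9 apart from the other genes, 6 higher and 3 lower in Tfam cKO. None of the 29 was past the threshold with an estimated correlation, where the lowest adjusted p was 0.801. That form of the test has only the 2 residual degrees of freedom, so hardly any list could pass it. Its adjusted p-values below therefore neither establish nor refute a call. In fry, which asks whether the genes of a list move on balance one way and does not compare them with other genes, the lowest adjusted p was 0.461. With the replicate number as a term, the members past the threshold over all genes numbered 7 in the ATF4 list, 4 in the keratinocyte list, 3 in the macrophage list and at most 2 in each other list. Targets of ATF4 and the integrated stress response, which is switched on by amino acid shortage and mitochondrial stress, stood highest, with a median log2 fold change of 0.31 that was 0.24 above the median of all genes (camera adjusted p = 1.6e-07; adjusted p = 0.801 with an estimated correlation). Both Tfam cKO libraries were above both WT libraries for 17 of its 33 tested members and below for 0. Over all tested genes that held for 25.4% higher and 9.75% lower, where chance gives 16.7% in each direction. No member passed over all genes and 10 were higher when adjusted over the list alone. Among these, chosen after their values were seen, the transcription factor gene Atf5 averaged 9.10 ± 0.162 FPKM in WT and 18.2 ± 3.69 FPKM in Tfam cKO, the asparagine synthetase gene Asns 8.26 ± 2.24 and 14.7 ± 1.73 FPKM, the glutathione-degrading enzyme gene Chac1 4.35 ± 1.33 and 12.3 ± 6.87 FPKM, and the mitochondrial folate enzyme gene Mthfd2 11.9 ± 4.75 and 22.2 ± 2.72 FPKM (SD, n = 2 each). The 2 members of highest level were Atf3, at 1475 ± 42.8 and 1642 ± 66.6 FPKM, and Atf4, at 368 ± 41.3 and 466 ± 10.7 FPKM. The median difference was 0.37 within the libraries numbered 1 and 0.42 within those numbered 2. Genes of tissue dissociation and early stress took 5.80% and 6.34% of the total FPKM in WT and 7.19% and 5.20% in Tfam cKO. That list was not called (median 0.14, camera adjusted p = 0.871). Its median was −0.04 after quantile normalization, 0.16 without WT 2 and 0.24 without Tfam cKO 2. A fit with a library left out has 1 in a group, so list medians are given for such fits without p-values.

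Lysosomal genes had a median log2 fold change of 0.22 (camera adjusted p = 0.000903; adjusted p = 0.801 with an estimated correlation), with 19 of 29 members higher in both Tfam cKO libraries than in both WT libraries and 0 lower. Cd63, a lysosomal tetraspanin, averaged 105 ± 4.77 FPKM in WT and 195 ± 44.2 FPKM in Tfam cKO, and Psap, the precursor of the saposins, 167 ± 7.26 and 185 ± 20.4 FPKM. Cd63 passed with the replicate number as a term (limma adjusted p = 0.0101, up to 1 under other alternatives). Glycolysis genes had a median of 0.24 (camera adjusted p = 0.00467; adjusted p = 0.801 with an estimated correlation), with 14 of 21 members higher in both Tfam cKO libraries and 1 lower. The aldolase gene Aldoa averaged 284 ± 14.4 and 370 ± 17.3 FPKM, and Pkm, which encodes pyruvate kinase, 243 ± 12.3 and 307 ± 34.7 FPKM. Cytosolic ribosomal protein genes had a median of 0.18 (camera adjusted p = 0.0207, and 0.953 with an estimated correlation). It was 0.03 after quantile normalization, where the camera adjusted p was 0.204. Within the libraries numbered 1 and 2 the median differences were 0.27 and 0.24 for lysosomal and 0.26 and 0.25 for glycolysis genes. That of the ribosomal genes was −0.03 within the libraries numbered 1 and 0.39 within those numbered 2. No member of the lysosomal, glycolysis or ribosomal lists passed over all genes or adjusted over the list alone. The glycolysis and lysosome calls ended without WT 1, where their medians were larger, at 0.35 and 0.28, but so was the median of all genes, at 0.13. They also ended without Tfam cKO 1, with medians of 0.185 and 0.180. The ribosomal call ended without WT 2 (median 0.06) and without Tfam cKO 2 (0.13). It ended too with the filter at 5 FPKM (camera adjusted p = 0.092) and with the replicate number as a term (0.0539).

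Nuclear genes of the mitochondrion did not stand apart. The median log2 fold change was 0.03 for the 37 genes of OXPHOS complex I, 0.08 for the 40 nuclear genes of complexes II to V, 0.12 for the 76 mitochondrial ribosomal protein genes, 0.07 for the 22 genes of mtDNA maintenance and transcription, 0.11 for the 26 genes of the TCA cycle and pyruvate entry and 0.05 for the 22 genes of fatty acid oxidation, against 0.07 for all genes. The camera adjusted p of these lists lay between 0.616 and 0.871, and none of their members passed over all genes or adjusted over the list alone. The signs of the complex I, complexes II to V, fatty acid oxidation and mtDNA maintenance medians turned negative after rescaling to equal totals. Ndufa6, a complex I subunit gene, averaged 156 ± 10.6 FPKM in WT and 147 ± 8.69 FPKM in Tfam cKO. Ndufa3, also of complex I, averaged 134 ± 12.8 and 99.8 ± 22.6 FPKM, and Polg, of mtDNA maintenance, 40.9 ± 5.06 and 31.6 ± 1.93 FPKM. Both were lower in both Tfam cKO libraries than in both WT libraries (limma adjusted p = 0.846 each). In that comparison 6 complex I genes were higher and 1 lower, and 5 genes of mtDNA maintenance were higher and 3 lower. Cox4i1, a subunit gene of cytochrome c oxidase, averaged 364 ± 43.0 and 394 ± 0.457 FPKM. Mitochondrial chaperones and proteases (median 0.16, adjusted p = 0.457), mitochondrial dynamics and mitophagy (0.15, adjusted p = 0.457), cholesterol biosynthesis and uptake (0.13, adjusted p = 0.616), NRF2 targets (0.13, adjusted p = 0.101), p53 and apoptosis genes (0.09, adjusted p = 0.738) and TGF-beta and BMP signalling (0.09, adjusted p = 0.373) were not called by camera, and the medians of the p53 and TGF-beta lists turned negative after rescaling. The median of the mitochondrial ribosomal list was 0.22 without WT 1, against 0.13 for all genes. That of the cholesterol list was 0.31 without WT 2, against 0.01 for all genes. Without WT 2 the median was −0.11 for complexes II to V and −0.29 for the cell cycle list. Without WT 1 the cell cycle median was 0.37, so its sign depended on which WT library was left out. With all libraries the cell cycle median was 0.06 (camera adjusted p = 0.674), and −0.04 after rescaling.

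Among immune functions, the inflammatory cytokine and chemokine list was lower in Tfam cKO, with a median log2 fold change of −0.14 over 19 genes (camera adjusted p = 0.00992; adjusted p = 0.801 with an estimated correlation). Of its members, 5 were lower and 4 were higher in both Tfam cKO libraries than in both WT libraries, and Cxcl2 was lower when adjusted over the list alone. The list of antigen uptake and phagocytosis receptors was also placed lower, with a median of −0.06 over 12 genes (camera adjusted p = 0.0201; adjusted p = 0.801 with an estimated correlation). There Clec7a was lower when adjusted over the list alone, Clec4n, the gene for Dectin-2, averaged 85.3 ± 10.2 FPKM in WT and 58.2 ± 6.20 FPKM in Tfam cKO, and the Fc receptor chain gene Fcer1g 334 ± 5.01 and 321 ± 32.3 FPKM. Both calls ended without WT 1 (medians −0.12 for cytokines and −0.04 for uptake receptors) and without Tfam cKO 2 (−0.08 and −0.03). The uptake receptor call also ended without a low-value filter, where the median was 0.0027 over 25 genes (adjusted p = 0.307). Within the libraries numbered 1 and 2 the median differences were −0.01 and −0.34 for cytokines and −0.06 and 0.01 for uptake receptors. In the dendritic cell maturation and migration list, which was not called (median 0.02, camera adjusted p = 0.249), Ccr7 and Ccl22 were lower when adjusted over the list alone. Without WT 1 the list median was 0.09, against 0.13 for all genes. Ccl22, a chemokine gene chosen after its values were seen, was listed at 16.2 and 46.3 FPKM in WT and 7.45 and 9.08 FPKM in Tfam cKO. MHC class II genes had a median of −0.06 (camera adjusted p = 0.249), with Cd74 at 9824 ± 757 and 10802 ± 2176 FPKM, and a median of −0.19 without Tfam cKO 1. MHC class I genes had a median of 0.09 (adjusted p = 0.890) and type I interferon response genes one of 0.10 (adjusted p = 0.616). The medians of the class I, interferon and maturation lists turned negative after rescaling to equal totals.

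**Figure D2:**
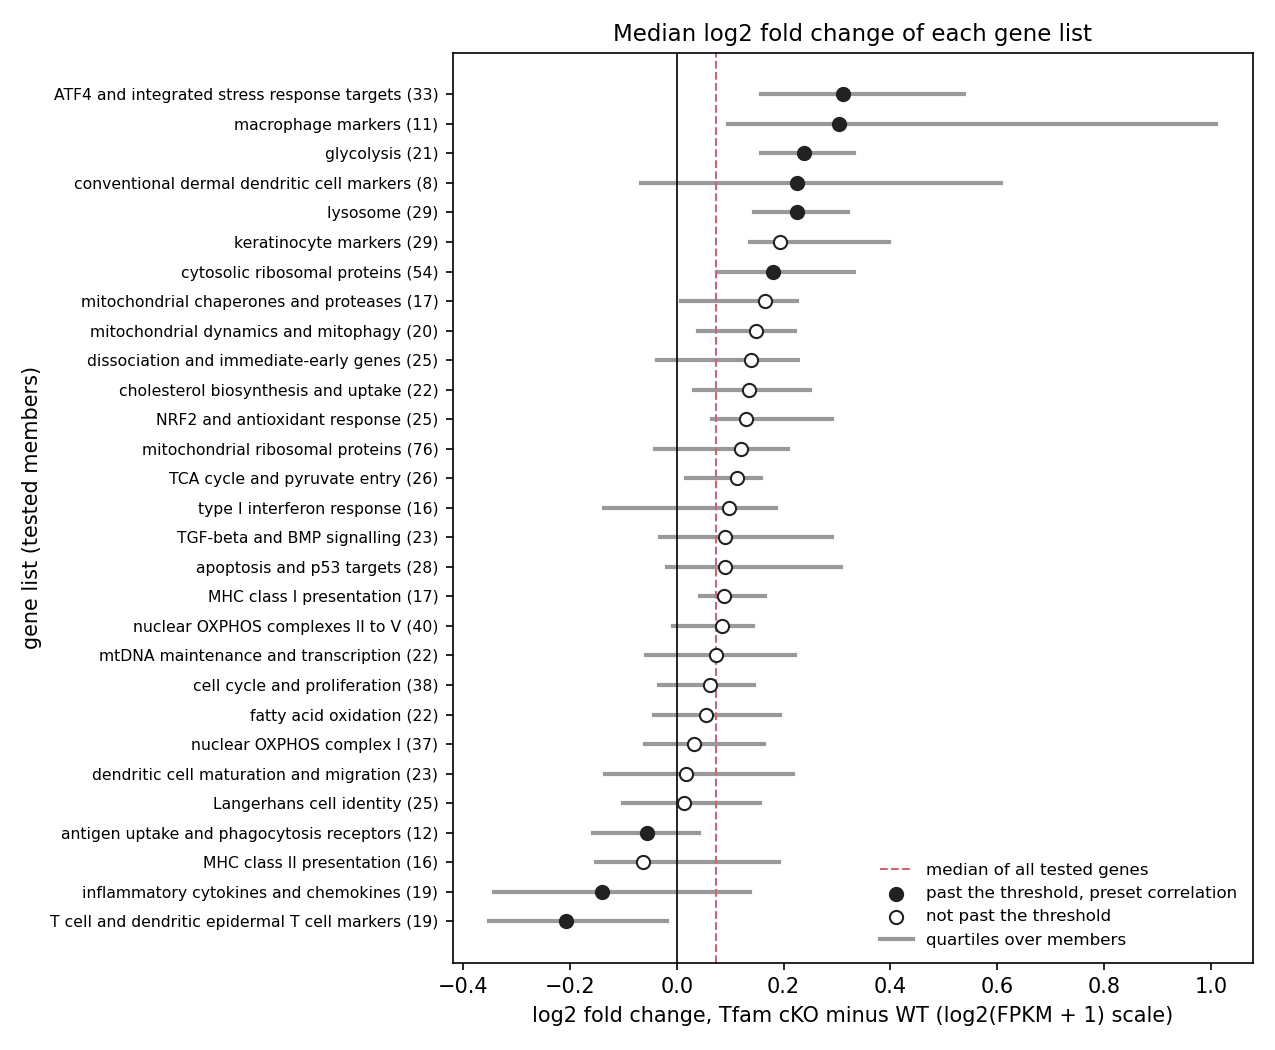
Median log2 fold change (points, Tfam cKO minus WT, on the log2(FPKM + 1) scale) and quartiles over members (bars) of the 29 tested gene lists. Filled points passed camera with the preset correlation, the ATF4 list has the highest median at 0.31, and the dashed line marks the median of all genes at 0.07.

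Transcripts listed as markers of other skin cells were present in all 4 libraries. Keratinocyte markers, led by Krt5 and Krt14, took 4.65% and 3.57% of the total FPKM in WT and 4.36% and 4.29% in Tfam cKO. Krt5 averaged 3801 ± 1128 FPKM in WT and 4147 ± 471 FPKM in Tfam cKO, and the keratinocyte list, with a median log2 fold change of 0.19, was not called (camera adjusted p = 0.0718). It was placed higher with the replicate number as a term (camera adjusted p = 0.0101), after rescaling to equal totals (median 0.07, adjusted p = 0.0267) and with no mean trend (0.0376). With the filter at 5 FPKM it was not (0.254). Without Tfam cKO 1 its median was 0.30. T cell markers, which include those of dendritic epidermal T cells, took 0.137% and 0.185% in WT and 0.0970% and 0.158% in Tfam cKO. Their list was called lower, with a median of −0.21 (camera adjusted p = 0.00137, and 0.892 with an estimated correlation). The difference was −0.29 within the libraries numbered 1 and 0.01 within those numbered 2. The call ended without Tfam cKO 1, with a median of 0.08, and without WT 2, with a median of 0.003. Macrophage markers were called higher, with a median of 0.30 over 11 genes (camera adjusted p = 0.0019; adjusted p = 0.801 with an estimated correlation), and C1qa, C1qb and C1qc were the members higher when adjusted over the list alone. Other members were Apoe, at 1139 ± 140 and 1376 ± 135 FPKM, and Adgre1, which encodes F4/80, at 86.1 ± 7.66 and 87.3 ± 14.8 FPKM. The list does not by itself show macrophages among the cells. A set of 9 macrophage markers other than C1q, Apoe and Adgre1 summed to at most 1.38 FPKM in each library. Markers of conventional dermal dendritic cells had a median of 0.23 over 8 genes (camera adjusted p = 0.0347; adjusted p = 0.892 with an estimated correlation). Of these, chosen after their values were seen, the lectin gene Mgl2, at 5.08 ± 0.0853 and 11.8 ± 1.71 FPKM, and Batf3, at 1.31 ± 0.256 and 3.40 ± 0.154 FPKM, were higher when adjusted over the list alone. The call ended without WT 1 (median 0.24), without Tfam cKO 1 (median 0.10) and without a low-value filter (median 0.03 over 14 genes, camera adjusted p = 0.255). Within the libraries numbered 1 and 2 the median differences were 0.27 and 0.50 for macrophage and 0.33 and 0.12 for dermal dendritic cell markers. Markers of melanocytes, monocytes and neutrophils, mast cells and basophils, B and NK cells, fibroblasts and endothelium, and erythroid cells had too few tested members for a test, and each of these lists took at most 0.049% of the total FPKM in any library. Xist was listed at 64.6 and 5.38 FPKM in WT and 39.0 and 45.6 FPKM in Tfam cKO. The summed Y-linked genes were listed at 0 in WT 1 and Tfam cKO 1, at 58.8 FPKM in WT 2 and at 21.7 FPKM in Tfam cKO 2. The groups were thus not matched in sex-linked transcripts within the libraries numbered 2, and no fit adjusted for this.

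**Figure D3:**
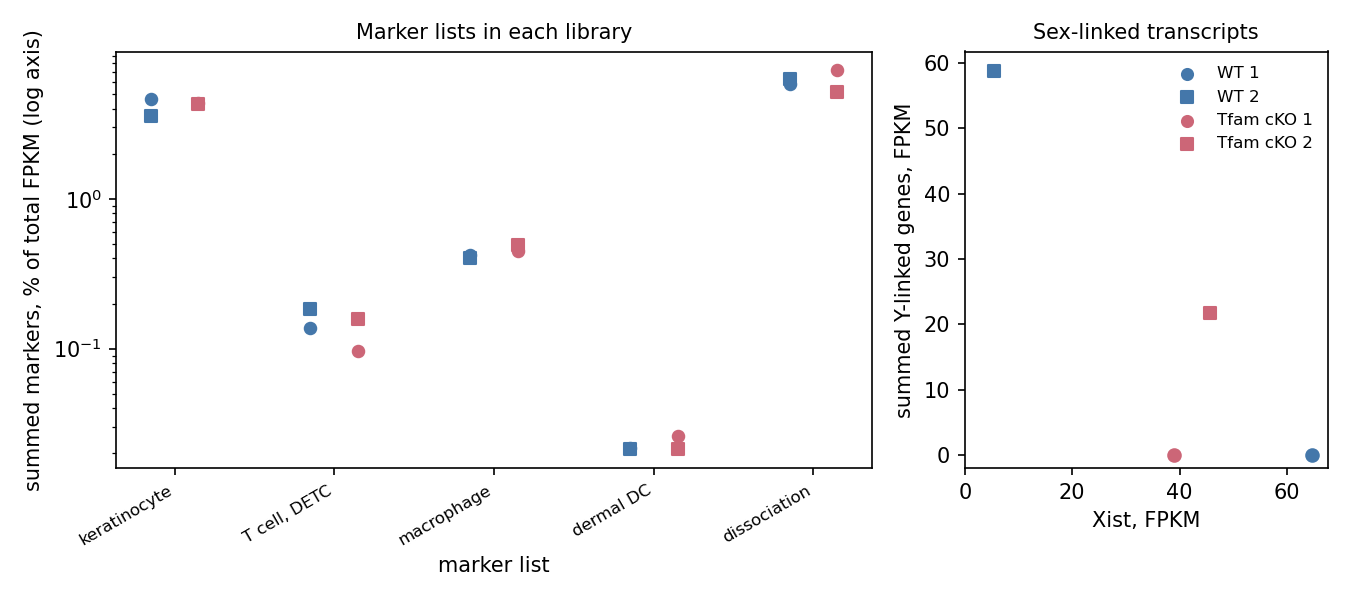
Left, summed FPKM of 5 marker lists as a percentage of the total FPKM of each library (log axis); right, summed FPKM of Y-linked genes against Xist FPKM. Circles are replicate 1 and squares replicate 2 of WT (blue) and Tfam cKO (red), and Y-linked transcripts appear at 58.8 FPKM in WT 2 and 21.7 FPKM in Tfam cKO 2.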

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

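The filter on effective fragments and the separate rows for symbols with several loci were chosen after seeing the data; the other alternatives were not. Counts of 2 genes higher and 0 lower were also found with quantile normalization, rescaling to equal totals, pseudocount 0.1, a fold change minimum, an adjusted p below 0.1, markers of other cell types left out, and symbols with several loci as separate rows. Genes higher numbered 0 without a filter, where 16426 genes were tested, 1 with the filter at 5 FPKM (Rmrp), 1 with pseudocount 5 (Rmrp), and 1 with a mean of at least 10 effective fragments, which removes Rmrp and leaves Amd1. Robust moderation gave 3 higher (Rab7b added) and 2 lower (Gm5741 and Hap1), and the fit without the mean trend 1 lower (Gm5741); Gm5741 is named after its values were seen. Leaving out a library gave 23 to 63 genes higher and 3 to 38 lower, with the lone library assumed to vary like the other group. The replicate block gave 145 higher and 39 lower; the labels do not say that the numbers pair the libraries, and the correlation of deviations was 0.255 across genes. The cause of these differences in count was not tested.

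Tfam kept its sign under its 12 alternatives, between −0.69 without WT 2 and −0.01 without WT 1, and passed the threshold in none; the filter at 5 FPKM removes it. The test with an estimated correlation has only 2 residual degrees of freedom, so hardly any list could pass it. With it the number of lists called was 0 of 29, against 9, and of lists of other cell types 0, against 3. With fry, which asks another question, whether a list's genes move on balance one way, both numbers were 0. The other settings called 7 to 11 lists. ATF4 targets (medians 0.19 to 0.48) and macrophage markers (0.18 to 0.40) were called higher under each of 13 alternatives with the preset correlation. Calls of lists counted here include fits that leave 1 library in a group, whose p-values assume that it varies like the other group. The camera direction of the cell cycle list, not called with all libraries and lower than the other genes, turned to higher without WT 1 (median 0.37), and its median, 0.06 with all libraries, turned negative without WT 2 (−0.29). Directions turned also for the T cell list without Tfam cKO 1 (−0.521 to 0.0839) and Hba-a1, a hemoglobin gene, without Tfam cKO 1 (log2 fold change −1.40 to 1.08). Of the 84 named genes other than Tfam, 38 changed sign under some alternative, 35 of which passed the threshold under none; the others were Hba-a1 and the sex-linked Ddx3y (−0.75 with all libraries, −3.18 to 1.69) and Xist (1.08, −0.60 to 2.76). The cause was not tested. Of the remaining values for lists, 344 stayed on their side of the threshold, 18 lost and 12 gained a call. Of those for named genes other than Tfam, 51 moved by more than the standard error, 54 gained and 3 lost a call, and the others, apart from Hba-a1, stayed close to the reported value or on its side of the threshold. No value for the mRNAs of mitochondrial DNA was possible under any alternative. With 9 or fewer fragments behind Rmrp, its fold is limited by depth.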

Other observations

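The tests of the explanations weighed in this part, the histone genes and the comparison by replicate number were chosen after the results were seen, while the gene lists and the alternatives for C1qc were fixed before the data were examined. By limma, 20 genes were called between the libraries numbered 2 and those numbered 1, among them Y-linked genes and pseudogenes. The genes named here were chosen after their values were seen. Klk5, an epidermal protease gene, was listed at 8.54 and 8.97 FPKM in WT 2 and Tfam cKO 2 and at 1.04 and 0.506 FPKM in WT 1 and Tfam cKO 1. Klk7, another epidermal protease gene, was at 9.39 and 19.99 FPKM against 1.23 and 1.29 FPKM, the envelope precursor gene Ivl at 4.13 and 6.17 against 0.833 and 0.744 FPKM, and Sbsn at 98.4 and 146 against 38.8 and 29.3 FPKM. The imprinted gene H19 went the other way, with 27.4 and 46.7 FPKM in the libraries numbered 1 and 4.11 and 8.54 FPKM in those numbered 2. The keratinocyte list had a median log2 difference of −0.07, replicate 2 minus 1. Tfam cKO 2 held both Xist, at 45.6 FPKM, and Y-linked transcripts, at 21.7 FPKM, while WT 2 held 5.38 and 58.8 FPKM.

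Replication-dependent histone genes, whose mRNAs end without a poly(A) tail, had a median log2 fold change of 0.37 over 43 genes, against 0.07 for all genes, with 17 of the 43 higher in both Tfam cKO libraries than in both WT libraries. The median was 0.31 after quantile normalization and 0.35 after rescaling to equal totals. The cell cycle list had a median of 0.06, with −0.31 within the libraries numbered 1 and 0.41 within those numbered 2. The ribosomal RNA precursor gene Rn45s averaged 218 ± 22.0 FPKM in WT and 383 ± 97.7 FPKM in Tfam cKO (SD, n = 2 each; limma adjusted p = 0.581).

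The first pattern is the pair of called genes, Amd1 and Rmrp. For Amd1, a different division of reads between the overlapping Amd1 and Amd2 models stays open, because Amd2 averaged no lower in FPKM (log2 fold change 0.047, 95% limma interval −0.353 to 0.447, against −0.354 needed to make up the rise of Amd1), but in fragments scaled to the depth of WT 1 it changed by −81.6 (SE 68.4), while Amd1 gained 151. For Rmrp, a larger amount of RNA without a poly(A) tail in the Tfam cKO libraries is a candidate explanation for part of the rise. The histone median was at percentile 100 of 10000 random lists matched on expression, which takes genes as independent. That median was 0.37, against a log2 fold change of 3.0 for Rmrp, so a gain of that size would not account for the whole rise. It stays open whether such RNA differed in the cells or in library preparation. Of the 3 splits of the 4 libraries, 2 gave at least as many calls, with 2 for genotype and 20 for replicate number, which points to a structure of the samples by that number; 3 splits are too few for a share under 0.05.

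The second pattern is the higher level of C1qa, C1qb and C1qc in Tfam cKO, whose summed FPKM was 26.1 and 35.2 in WT and 128 and 74.0 in Tfam cKO. Dermal macrophages among the sorted cells are argued against, because 9 other macrophage markers (Mrc1, Folr2, Cd163, Lyve1, Pf4, Ms4a7, Cd209f, Trem2 and Fcgr1) changed by −0.191 FPKM in sum and stayed at or below 1.38 FPKM in each library, against a rise of 70.1 FPKM for C1q. This covers only cells that express those 9 genes. In the macrophage list fixed beforehand, 6 of 11 tested members were higher in both Tfam cKO libraries and 0 lower. The C1q genes and Apoe (1139 and 1376 FPKM on average) were among the 6, while Adgre1 averaged 86.1 and 87.3 FPKM. A larger share of Langerhans cells is argued against by the identity list, whose median was 0.0124 (bootstrap interval −0.05 to 0.09), against at least 1.42 for the C1q genes. Expression of C1q by Langerhans cells in the Tfam cKO libraries, or another difference between the animals, stays open as a hypothesis that was not tested and that would need C1q measured in single cells. Among fits with all 4 libraries, C1qc passed the threshold over all genes only with the replicate number as a term.

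The third pattern is the higher level of ATF4 targets in Tfam cKO. A larger share of keratinocytes stays open: the ATF4 median exceeded the keratinocyte median by 0.118, and by at least 0.0748 in each of the 4 pairings of a WT with a Tfam cKO library, which share libraries, but the bootstrap interval of 0.00317 to 0.267 takes genes as independent and became −0.176 to 0.497 once widened for the estimated correlation between genes. Stress of cell preparation stays open too, with a difference of 0.174 against the dissociation list (interval 0.0562 to 0.375, widened −0.247 to 0.89) that was −0.0205 in 1 of the 4 pairings. Within the libraries numbered 1 and those numbered 2, the median changed by 0.37 and 0.42 for ATF4 targets, by 0.04 and 0.35 for keratinocyte markers, and by 0.31 and −0.17 for the dissociation list. An integrated stress response to impaired mitochondria is the hypothesis the design offers, not tested here, and a test would need the mRNAs of mitochondrial DNA, which were not analysed here.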
